A study of Homo sapiens with 12 samples.

How the data were processed

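RNA from SW48 cells, an established human colorectal cancer line, was measured on Illumina HumanWG-6 v3 expression arrays, on which each probe gives 1 signal per array. The 12 arrays fell into 4 groups of 3 by the treatment in the labels: untreated control, 5'-Aza-cytidine (azacytidine, a cytidine analog that blocks DNA methyltransferases) at 1 µM for 5 days, Trichostatin A (TSA, a histone deacetylase inhibitor) at 0.5 µM for 2 days, and azacytidine for 5 days followed by TSA for 2 days, called the combined treatment here. The arrays came from 2 chips of 6 arrays, and both chips held all 4 groups, but not evenly. Chip 1 held replicates 1 and 2 of control and TSA and replicate 1 of azacytidine and the combined treatment. Chip 2 held the other arrays, so more of the arrays with azacytidine lay on chip 2. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples. Treatment times differ between the groups. If time in culture differed with them, it cannot be told apart from treatment in any comparison.

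The authors summarised the scanned arrays with GenomeStudio, per the submitters' processing notes, and deposited 1 intensity per probe and array on a linear scale, without normalization between arrays and without background subtraction, as the values show. The deposited table also gives a detection p-value per probe and array, per the file headers, in steps that fit a ranking against about 759 control probes. A second deposited table holds the authors' processed values, which behave as log2 values quantile-normalized between arrays, with array medians all near 7.63. The submitters' processing notes name lumi 2.6.0. Which transform was applied is not given in the sources used here, and the low end of these values is compressed, so they served as an alternative only. No genome build is given in the sources used here, so no coordinates are printed.

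Of the deposited rows, 48801 had a probe ID and values, 1 was blank and 1 had values without an ID. The platform annotation listed 27590 of these probes, of which 27577 had 1 gene symbol and 13 had several genes. The remaining 21211 probes are unnamed here. Symbols were looked up by Entrez gene ID in the RefSeq gene table, which matched 27540 probes and changed 0 symbols. A gene was represented by its probe with the highest mean over the 12 arrays. Among 1937 genes with several kept probes, 71 had probes called in opposite directions after azacytidine, 0 after TSA and 120 after the combined treatment, and none of the genes named for those comparisons was among them.

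Intensities were background-corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, using the detection p-values and an offset of 16, then quantile-normalized and taken to log2. Probes with a detection p under 0.01 on at least 3 of the 12 arrays were kept, which left 13915 probes, 11694 of them with 1 gene, and 9484 genes. The raw median signal per array lay between 117 and 135, and the raw minimum between 64.6 and 80.6, so most probes lay near background.

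One linear model with 4 group means was fitted over the 12 arrays with limma, and 5 group contrasts and the interaction (the azacytidine change with TSA minus that without TSA) were tested with moderated statistics, two-sided, with Benjamini-Hochberg adjustment over the genes of each contrast and a threshold of 0.05. Errors given as SE come from this fit, with n = 3 arrays per group. A gene below detection on all arrays of a group has only a bound there. The bound is the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own, on normalized log2 values. It is written as "at least N-fold", beside the fitted log2 change, which depends on the background correction.

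The tests, the alternatives, 22 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. For each treatment against control the rule names the 6 largest increases and 6 largest decreases past the threshold without overlap between the groups' arrays, up to 3 members per list past the threshold with the largest change, and 10 preset genes, of which 7 were tested. For the interaction and for the combined treatment against each single one it names the 5 largest each way. Not every gene the rule allows is printed. Probes of near-identical family members can bind each other's transcripts, so single members of the GAGE, CT45A, VCX, PAGE, MAGEA, MBD3L and LGALS7 families, of the metallothionein and histone genes, and HBA1 and HBA2 are uncertain. After the first results had been seen, the step that updates list symbols was corrected. It had dropped GAGE4 and GAGE7, which the fixed cancer-testis list holds under those symbols. The correction moved that list from 43 of 45 tested members higher after azacytidine to 45 of 47.

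Same-numbered arrays were checked for pairing through their deviations from the group means. For the combined treatment against azacytidine all 3 correlations were above 0.1, from 0.197 to 0.418, and in no other comparison were all 3. There the same-numbered arrays also shared a chip, so pairing by number cannot be told apart from the chip. The alternatives covered background correction, normalization, the authors' values, the probe filter, several probes per gene, chip and replicate number as blocks, each chip alone, the arrays in the fit, moderation, array weights, thresholds, leaving out each array and the correlation of camera. On simulated data with 200 of 9484 genes changed in TSA against control, the fit recovered 71.2% of changes of 0.5 log2, 99.2% of 1 log2 and 100% of 2 log2, with 4.38% false calls. For azacytidine against control the shares were 73.3%, 98.8% and 100%, with 4.62% false calls. In the simulated TSA comparison camera called 20 of 20 lists of 20 genes shifted by 0.3 log2 and 1 of 20 unshifted lists, at an unadjusted p under 0.05. The simulated noise was independent between genes, without chip effects, so it cannot show false list calls where genes are correlated. Changes were added after normalization and to few genes, so effects of wide changes on normalization were not simulated.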

Results

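Gene expression was measured in SW48 cells, a colorectal cancer line described in the labels as microsatellite-instable, after treatment with azacytidine, TSA or both in sequence, with 3 arrays for each treatment and 3 for untreated control. Between 11742 and 13647 of 48801 probes were detected per array. The 6 arrays with azacytidine had 12886 ± 483 detected probes (SD, n = 6) and the 6 without had 12145 ± 413 (SD, n = 6), a difference of 741 (two-sided exact permutation test, p = 0.0238 over 924 splits). These splits ignored the chip, and more of the arrays with azacytidine lay on chip 2, so part of this difference may come from the chip. The first principal component held 84.3% of the variance and separated arrays with azacytidine from those without. The second held 8.13% and separated the combined treatment from azacytidine alone. The third held 2.26% and followed the chip. Correlations within groups were 0.991 to 0.996 across genes, and those between TSA and control arrays 0.990 to 0.996. Genes are not independent replicates.

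**Figure D1:**
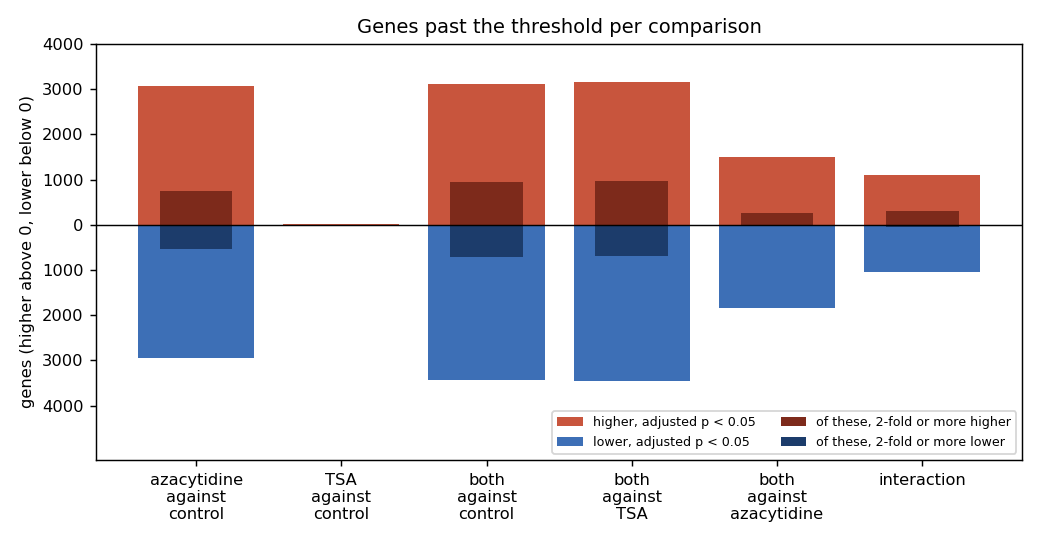
Genes past an adjusted p of 0.05 in limma for each comparison, out of 9484 tested, with higher genes above 0 and lower genes below, and those changed by 2-fold or more as narrow dark bars. "Both" is azacytidine followed by TSA. Azacytidine against control gave 6023 genes and TSA against control gave 14.

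The first comparison asked what azacytidine alone changed. Germline genes that control cells did not detectably express appeared at high signal. GAGE7 was at least 242-fold higher (log2 change 9.39 ± 0.12 SE, n = 3, adjusted p = 2.5e-15), GAGE4 at least 233-fold (8.97 ± 0.13 SE) and CT45A3 at least 132-fold (8.49 ± 0.14 SE), all members of cancer-testis families normally expressed in the germline. PAGE2 and PAGE5 were at least 43.9-fold and at least 39.9-fold higher, and VCX, detected on the control arrays too, rose by 7.21 ± 0.12 SE. The largest decreases were in KRT16, a stress keratin (log2 change −4.66 ± 0.16 SE, at least 14.4-fold lower), DDIT4, a stress-induced inhibitor of mTOR signalling (−4.20 ± 0.07 SE), EPS8L1 (−4.15 ± 0.17 SE, at least 11.6-fold lower), LEMD1 (−3.79 ± 0.11 SE), and ALDOC and NDRG1 (−3.24 ± 0.08 and −3.21 ± 0.09 SE).

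Of 47 tested cancer-testis and germline genes, 45 rose and 0 fell after azacytidine (median log2 change 3.30, or 1.63 with genes below background at their bound, camera adjusted p = 1.2e-26, and 2.16e-05 with an estimated correlation). Of 95 listed genes 78 had a probe, and a gene silent in control cells was tested only if treated arrays detected it, which favours increases. Without the filter on dim probes the adjusted p of the cancer-testis list was 2.83e-27, with a mean shift of 2.21 against 3.52. Of 19 tested genes known to be hypermethylated in colorectal cancer, 16 rose and 2 fell (median 1.82, or 0.70 with bounds, adjusted p = 8.19e-07, 0.00462 with an estimated correlation, and 0.00494 without the filter, where the mean shift was 0.531 against 1.93). They included DKK1, a secreted WNT antagonist (log2 change 5.44, at least 17-fold), VIM, the mesenchymal intermediate filament (4.78, at least 15.1-fold), and UCHL1, a neuronal deubiquitinase (4.17, at least 4.69-fold). Imprinted genes rose in 12 of 22 and fell in 3 (adjusted p = 0.00852, 0.0519 with an estimated correlation, and 0.00729 without the filter, where the mean shift was 0.613 against 1.03), led by the noncoding RNA MEG3 (6.98, at least 39.6-fold) and its neighbour DLK1 (5.39, at least 13.2-fold). Neuronal and neuroendocrine genes rose in 9 of 17 and fell in 3 (adjusted p = 0.0322, and 0.0891 with an estimated correlation), with the neurofilament gene NEFH at least 6.74-fold higher. The neuronal call was lost without the filter (adjusted p = 0.0836, mean shift 0.42 against 0.94) and at a detection p of 0.05 (0.0538). Haematopoietic and endothelial markers rose in 5 of 7 and fell in 1 (adjusted p = 0.0145, 0.143 with an estimated correlation, and 0.0955 without the filter, where the mean shift was 0.378 against 1.496), with VWF at least 2.21-fold and the globin gene HBA1 at least 2.59-fold higher.

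Hypoxia and glycolysis genes fell in 24 of 27 and rose in 2 (median log2 change −0.77, adjusted p = 3.67e-07, and 0.0176 with an estimated correlation). ANKRD37, a hypoxia-inducible gene, changed by −3.02, and LDHA, the lactate dehydrogenase subunit gene, by −1.34, while BNIP3 rose by 2.19 (at least 1.60-fold). ATF4 and unfolded protein response genes fell in 15 of 26 and rose in 5 (adjusted p = 0.00469, and 0.0519 with an estimated correlation), with TRIB3 at −2.72 and the asparagine synthetase gene ASNS at −2.60. Cholesterol synthesis genes fell in 12 of 22 and rose in 5 (adjusted p = 0.0322, and 0.0891 with an estimated correlation), led by SCD, which makes monounsaturated fatty acids (−2.98), and INSIG1, a regulator of sterol synthesis (−2.47).

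Genes of the p53 response rose in 18 of 27 and fell in 5 (median 0.68, adjusted p = 0.0017, and 0.0893 with an estimated correlation). They included TP53I3 (log2 change 2.22 ± 0.08 SE), TP53INP1 (2.11 ± 0.08 SE), MDM2, which targets p53 for degradation (1.76 ± 0.14 SE, at least 2.03-fold), and the cell cycle inhibitor CDKN1A (1.19 ± 0.07 SE). Cell cycle genes fell in 24 of 52 and rose in 7 (median −0.20, adjusted p = 0.0417, and 0.143 with an estimated correlation), with the mitotic kinase gene AURKB at −1.10. Ribosome biogenesis and MYC target genes rose in 22 of 38 and fell in 7 (median 0.33, adjusted p = 0.037, and 0.0993 with an estimated correlation). The cell cycle call was also lost at a detection p of 0.05 (adjusted p = 0.0528), without azacytidine replicate 1 (0.0599), without control replicate 3 (0.0624), and on chip 1 alone (0.0593), where fewer arrays gave nearly the same mean shift (−0.26 against −0.27). The ribosome biogenesis call was lost under median scaling (0.1), without control replicate 2 (0.0515) and without azacytidine replicate 3 (0.0521).

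The other 11 lists did not pass the test after azacytidine, although members moved. Interferon-stimulated genes rose in 12 of 25 and fell in 9, with HERC5 at least 3.98-fold and IFI27 at least 4.64-fold higher and ISG15 at 2.67. Antigen presentation genes rose in 5 of 16 and fell in 8, mesenchymal and fibroblast markers rose in 7 of 12 and fell in 3, and histone genes rose in 10 of 21 and fell in 4. The mesenchymal list (adjusted p = 0.0594, and 0.26 with an estimated correlation) did pass under median scaling (0.0157), with the mean of a gene's probes (0.0247) and without control replicate 1 (0.046). Genes widely reported as induced by histone deacetylase inhibitors rose in 13 of 22 and fell in 6. Metallothionein genes rose in 2 of 8 and fell in 5, with MT3 at least 3.59-fold higher and MT1X at −1.08, so that their median was −0.45 and their mean 0.15. DNA methylation and chromatin modifier genes rose in 7 of 32 and fell in 9, with a median of 0.09 and a mean of −0.02. Intestinal differentiation markers rose in 2 of 7 and fell in 4, intestinal stem cell and WNT target genes rose in 9 of 18 and fell in 7, apoptosis regulators rose in 10 of 23 and fell in 8, and mismatch repair genes fell in 3 of 6. Adjusted over the list alone, counts were the same except 46 higher cancer-testis genes, 11 higher neuronal genes, 6 higher chromatin genes and 16 lower ATF4 genes.

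Among the preset genes, the de novo methyltransferase gene DNMT3B rose by 0.59 ± 0.09 SE (adjusted p = 9.42e-05), CDKN2A, the gene of the p16 cell cycle inhibitor, rose by 1.00 ± 0.17 SE (0.000199) and HDAC1 fell by 0.21 ± 0.07 SE (0.0257). The HDAC1 call was lost with only the 6 arrays compared (adjusted p = 0.0561), and without azacytidine replicate 1 (0.0968), control replicate 1 (0.0582) or control replicate 2 (0.0515). Its change there lay between −0.17 and −0.21. On chip 1, with 1 azacytidine array, and on chip 2, with 1 control array, it was −0.30 and −0.15. DNMT1, the maintenance methyltransferase gene whose protein azacytidine traps, had a log2 change of 0.01 ± 0.09 SE (adjusted p = 0.959), HDAC2 of 0.09 ± 0.07 (0.303) and HDAC3 of −0.13 ± 0.09 (0.209).

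In all, 6023 of 9484 genes passed the threshold in limma after azacytidine, 3067 higher and 2956 lower, of which 749 were higher and 540 lower by 2-fold or more. Of 10052 genes detected on no control array, 572 were detected on all 3 azacytidine arrays. Of 8003 detected on all control arrays, 119 were detected on no azacytidine array. Control arrays had the fewest detected probes (mean 11870, against 12869 for azacytidine and 12419 for TSA), so part of this imbalance may reflect detection. Median scaling in place of quantile normalization moved the median of all genes to −0.127 and the split to 1935 higher and 3179 lower, so small changes are relative to the normalization. With chip as a block 6435 genes passed, 5942 of them shared with the same direction.

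**Figure D2:**
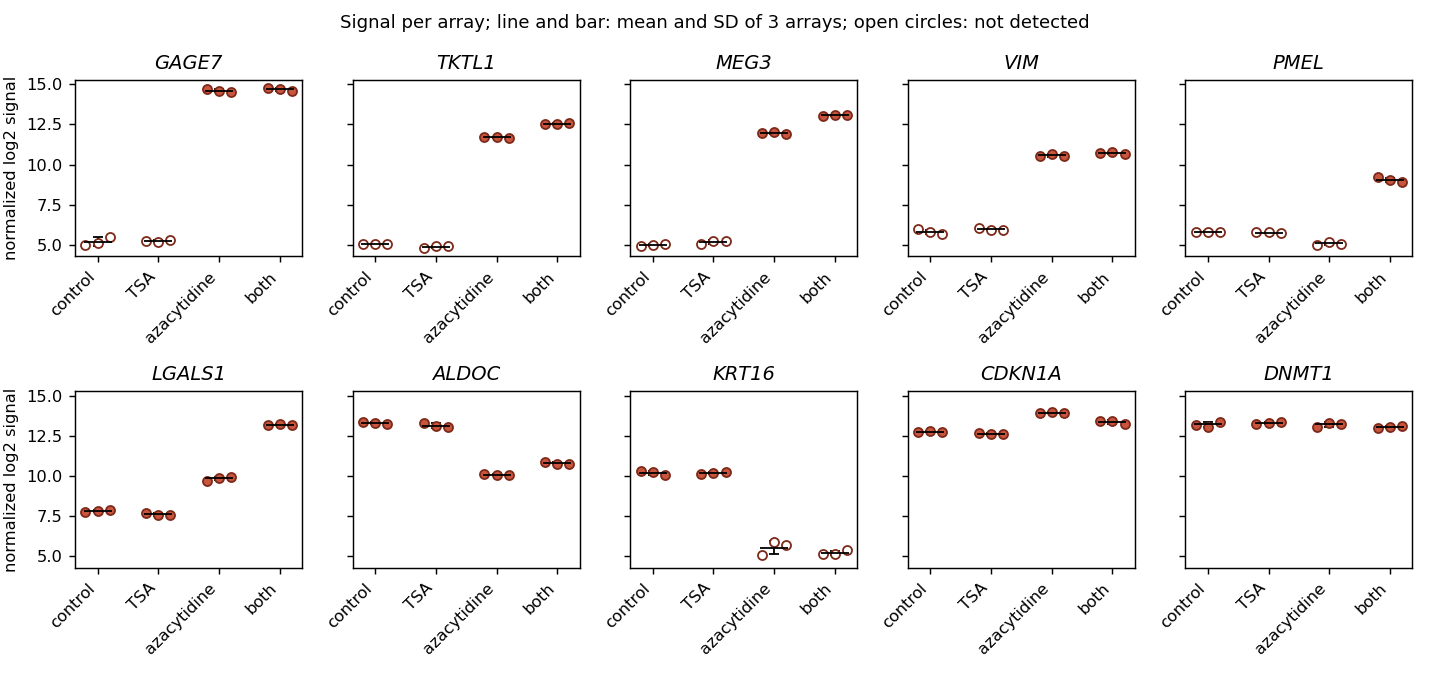
Normalized log2 signal of 10 named genes on each of the 12 arrays (vertical axis) by group (horizontal axis), with the mean as a line, the SD of 3 arrays as a bar, and open circles where the probe was not detected. GAGE7, TKTL1, MEG3 and VIM were not detected without azacytidine, PMEL was detected only on the combined arrays, and DNMT1 had a log2 change of 0.01 after azacytidine.

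The second comparison asked what TSA alone changed, and few genes did. SPATA13 rose by 1.17 ± 0.17 SE on the log2 scale (n = 3, adjusted p = 0.0169), IRF2BPL by 1.16 ± 0.16 SE, ZKSCAN1 by 1.10 ± 0.17 SE (at least 1.70-fold), ARHGAP44 by 0.93 ± 0.13 SE, PRR11 by 0.92 ± 0.13 SE (at least 1.11-fold) and MAL by 0.89 ± 0.13 SE. On the authors' values PRR11 and MAL had changes of 0.27 and 0.36 and did not pass (adjusted p = 0.0808 and 0.141). BAX, a proapoptotic p53 target, rose by 0.79 ± 0.10 SE. CD164L2 fell by 0.57 ± 0.08 SE and the metallothionein gene MT1X fell by 0.55 ± 0.09 SE, and under median scaling neither passed (adjusted p = 0.183 and 0.51). SPATA13 did not pass with array weights (0.0652). Of these 9 genes, none passed without TSA replicate 2 (adjusted p from 0.0745 to 0.138), only PRR11 without TSA replicate 1, and only IRF2BPL and ARHGAP44 with only the 6 arrays compared. Without control replicate 1 SPATA13, PRR11, MAL, BAX, CD164L2 and MT1X did not pass, and without TSA replicate 3 SPATA13, IRF2BPL, ZKSCAN1, PRR11, MAL and MT1X did not. SPATA13 (0.0712) and MAL (0.0545) did not pass without control replicate 3, nor MT1X (0.108) without control replicate 2. MT1X also lost its call on the authors' values, with either looser probe filter, with the replicate block and with other moderation (adjusted p from 0.0595 to 0.0839). Over the left-out arrays the change lay between 1.03 and 1.25 for SPATA13 and between 0.67 and 0.86 for BAX where the call was lost. CDKN1A, a gene widely reported to respond to histone deacetylase inhibitors, changed by −0.14 ± 0.07 SE (adjusted p = 0.7). DNMT1, DNMT3B, HDAC1, HDAC2, HDAC3 and CDKN2A had log2 changes from −0.06 to 0.11, and none passed.

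In all, 14 genes passed in limma, 12 higher and 2 lower, 3 of them by 2-fold or more, and 725 genes (7.64%) had an unadjusted p under 0.05. For 9440 of 9484 genes the 95% confidence interval lay within 2-fold either way. Some tested genes, such as GAGE7 and MEG3, were below detection on all TSA and control arrays, where a narrow interval does not show a lack of change. The arrays of both groups did not overlap for 11.2% of genes, against 10% by chance. Leaving out TSA replicate 2 gave 0 genes and control replicate 2 gave 24, so the count rests on single arrays. Each chip alone held fewer arrays, and chip 2 only TSA replicate 3 and control replicate 3 of these groups. The genes named above that passed after TSA kept their direction on each chip. On chips 1 and 2 SPATA13 changed by 0.97 and 1.56, BAX by 0.83 and 0.72, and MT1X by −0.68 and −0.27. Of the genes detected on no control array, 36 were detected on all 3 TSA arrays. Of those detected on all control arrays, 0 were detected on no TSA array. The lower detection on control arrays may favour this imbalance.

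After TSA, 4 of 22 lists passed the list test. Cell cycle genes shifted up by a median of 0.10 (52 tested, 0 passing singly, adjusted p = 5.08e-08, and 0.0147 with an estimated correlation). Genes widely reported as induced by histone deacetylase inhibitors shifted down by a median of −0.10, with 1 of 22 lower and 0 higher (adjusted p = 0.00145, and 0.0327 with an estimated correlation). On chip 2 alone, with 1 TSA and 1 control array, that list had a mean shift of −0.09. The metallothionein list (median −0.17, adjusted p = 0.0241) and the interferon list (median −0.08, adjusted p = 0.0446) had adjusted p-values of 0.272 and 0.26 with an estimated correlation. Both calls were lost under other settings, with adjusted p-values from 0.0512 to 0.0792 for metallothionein and from 0.0514 to 0.237 for interferon genes. On chip 2 alone their mean shifts were −0.11 and −0.03, against −0.15 and −0.08 over all arrays. In the other 18 lists at most 1 member passed. Among them the ribosome biogenesis list passed the list test with chip as a block (adjusted p = 0.0364, mean shift 0.05) and under cyclic loess (0.0274). Histone genes passed upward under median scaling (0.0233), at a detection p of 0.05 (0.0213), and without control replicate 2 (0.0222) or TSA replicate 3 (0.00467). The p53 list passed upward under median scaling (0.0233), under cyclic loess (0.0376) and without control replicate 2 (0.041). Hypoxia genes passed downward under median scaling (0.00203) and without control replicate 2 (0.016), and cancer-testis genes under cyclic loess (0.000752). Adjusted over the list alone, 3 histone genes were higher and 2 hypoxia genes and 1 mesenchymal marker lower, and other counts were the same.

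The third comparison set the combined treatment against control. Germline genes rose again, with GAGE7 at 9.49 ± 0.12 SE (at least 260-fold), and TKTL1, a transketolase-like cancer-testis gene, reached 7.51 ± 0.07 SE (at least 58.8-fold). MEG3 rose by 8.07 ± 0.08 SE (at least 84.2-fold), DKK1 by 6.33 ± 0.13 SE (at least 31.8-fold) and HBA2 by 5.85 ± 0.13 SE (at least 18.5-fold). The largest decreases were in KRT16 (−4.97 ± 0.16 SE, at least 14.4-fold lower), DDIT4 (−4.04 ± 0.07 SE), ANKRD37 (−3.53 ± 0.08 SE), EPS8L1 (−3.47 ± 0.17 SE), SCD (−3.29 ± 0.19 SE) and IGFL2 (−2.96 ± 0.09 SE).

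Lists that passed after the combined treatment, and also with an estimated correlation, were cancer-testis genes (47 of 47 higher, median 3.61, or 2.17 with bounds, adjusted p = 9.44e-28), colorectal cancer hypermethylated genes (16 of 19 higher, 1 lower, adjusted p = 1.3e-07) and neuronal genes (12 of 17 higher, 2 lower, adjusted p = 0.000264). So were imprinted genes (13 of 22 higher, 3 lower, adjusted p = 0.00375, with NNAT at least 5.64-fold higher) and genes induced by histone deacetylase inhibitors (15 of 22 higher, 4 lower, adjusted p = 0.00335, with SYT11 at least 8.92-fold, CPA4 at least 6.24-fold and ALPG at least 3.41-fold higher). Downward, cell cycle genes fell in 37 of 52 and rose in 2 (median −0.40, adjusted p = 0.000138), cholesterol synthesis genes fell in 14 of 22 and rose in 2 (adjusted p = 0.00573), and hypoxia and glycolysis genes fell in 21 of 27 and rose in 2 (adjusted p = 1.14e-05), while SLC2A3, a glucose transporter gene of that list, rose by 3.89. The histone list (15 of 21 higher, 2 lower, adjusted p = 0.0106), the metallothionein list (6 of 8 higher, 1 lower, adjusted p = 0.0262), the haematopoietic list (6 of 7 higher, 1 lower, adjusted p = 0.00177) and the ATF4 list (17 of 26 lower, 7 higher, adjusted p = 0.0107) had adjusted p-values of 0.258, 0.248, 0.0665 and 0.0603 with an estimated correlation. Genes of the p53 response rose in 16 of 27 and fell in 7, and the list did not pass (adjusted p = 0.0607). It did pass without the filter on dim probes (0.0183), at a detection p of 0.05 (0.0359), with the mean of a gene's probes (0.0336) and without combined replicate 2 (0.048). Its mean shift in these settings lay between 0.27 and 0.30. The mesenchymal list, not called either, passed upward without the filter (adjusted p = 0.0293), at a detection p of 0.05 (0.0278) and under median scaling (0.0381). It also passed with the mean of a gene's probes (0.0221) and without combined replicate 3 (0.0242). Mismatch repair genes passed downward without the filter (0.00996) and at a detection p of 0.05 (0.0338), and interferon genes upward under median scaling (0.0477). Ribosome biogenesis genes rose in 12 of 38 and fell in 12 (median 0.06, mean −0.04, adjusted p = 0.875). Leaving out control replicate 3 also lost the metallothionein call (adjusted p = 0.0521). Without the filter on dim probes, which favours increases, the haematopoietic mean shift was 0.713 against 2.777 (adjusted p = 0.0296). The hypermethylated, neuronal and imprinted lists still passed there, with mean shifts of 0.645, 0.842 and 0.696.

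In all, 6541 genes passed in limma against control, 3108 higher and 3433 lower, of which 947 and 713 changed by 2-fold or more. Median scaling moved the median of all genes to −0.339 and the split to 1624 higher and 4660 lower. CDKN1A rose by 0.59 (adjusted p = 1.25e-05), but by 0.17 with an adjusted p of 0.164 under median scaling. CDKN2A rose by 0.61 with overlapping arrays, and DNMT3B by 0.66. HDAC3 fell by 0.25, a call lost without control replicate 1 (change −0.19, adjusted p = 0.0815) or combined replicate 3 (−0.22, 0.0737). On chip 1, with 1 combined array, and on chip 2, with 1 control array, HDAC3 changed by −0.21 and −0.24. DNMT1, HDAC1 and HDAC2 had log2 changes of −0.15, −0.09 and −0.00 and did not pass. Adjusted over the list alone, 18 ATF4 genes and 22 hypoxia genes were lower, 9 WNT target genes higher and 7 lower, and other counts were the same.

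The fourth comparison asked what azacytidine changed in cells that later received TSA, through the combined treatment against TSA. The combined cells had azacytidine before their TSA and the TSA cells did not, so time in culture may differ here too. GAGE7 was at least 295-fold higher, MEG3 at least 95.4-fold and TKTL1 at least 66.6-fold, while KRT16 was at least 14.2-fold lower and DDIT4 changed by −3.81 ± 0.07 SE. Of 9484 genes, 6617 passed in limma, 3168 higher and 3449 lower, with 1661 changed by 2-fold or more. Across genes these changes correlated with those of azacytidine against control at r = 0.889 (Spearman's rho 0.831, slope 1.01, no arrays shared). The imbalance between chips was the same in both comparisons, so part of this correlation may come from the chip. Both comparisons shared 2392 higher and 2391 lower genes, against 1024 and 1075 for independent lists, and 169 genes were called in opposite directions. Median scaling moved the median of all genes to −0.391 and the split to 1485 higher and 4994 lower. Here 12 lists passed, 8 higher and 4 lower, and 8 also with an estimated correlation. They included cancer-testis genes with 47 of 47 higher, cell cycle genes with 39 of 52 lower and 1 higher, and genes induced by histone deacetylase inhibitors with 17 of 22 higher and 3 lower.

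**Figure D3:**
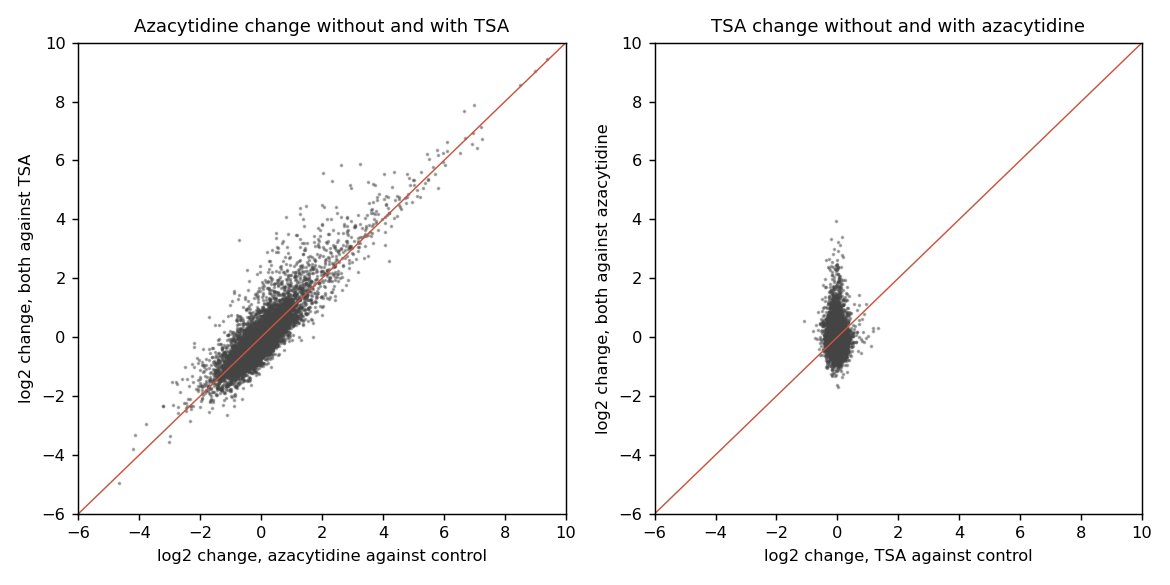
Log2 changes of 9484 genes (points), with the line of equal change. Left, azacytidine against control (horizontal) and the combined treatment against TSA (vertical), r = 0.889. Right, TSA against control (horizontal) and the combined treatment against azacytidine (vertical), r = −0.07, where the vertical spread is wider than the horizontal.

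The fifth comparison set the combined treatment against azacytidine, which differ by TSA and possibly by 2 further days of culture. The labels do not give the day on which the azacytidine cells were harvested, so a difference in culture time is an assumption. PMEL, a melanosome protein gene, was detected only on the combined arrays (log2 change 3.96 ± 0.08 SE, n = 3, at least 6.50-fold, adjusted p = 1.22e-11). VGF, a neuroendocrine secreted protein gene, rose by 3.41 ± 0.08 SE, LGALS1, the galectin-1 gene, by 3.35 ± 0.08 SE, HBA2 by 3.23 ± 0.13 SE and MBD3L5 by 3.12 ± 0.09 SE (at least 3.92-fold). Lower genes included SPATA18 (−1.69 ± 0.10 SE), TGFBI (−1.64 ± 0.10 SE), the zinc transporter gene SLC39A1 (−1.35 ± 0.11 SE), STAB1 (−1.31 ± 0.11 SE, at least 1.11-fold lower) and IFITM3 (−1.31 ± 0.09 SE).

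Metallothionein genes rose in 8 of 8 (median 0.82, adjusted p = 2.28e-06, and 0.0253 with an estimated correlation), and genes induced by histone deacetylase inhibitors rose in 14 of 22 and fell in 3 (median 0.46, adjusted p = 0.000256, and 0.0134 with an estimated correlation). CDKN1A, a member of that list, fell by 0.60. Neuronal genes rose in 8 of 17 with 0 lower, haematopoietic markers in 6 of 7 with 0 lower, colorectal cancer hypermethylated genes in 9 of 19 with 1 lower, and cancer-testis genes in 17 of 47 with 9 lower, and each list also passed with an estimated correlation (adjusted p = 0.0134, 0.0335, 0.0423 and 0.0134). Cell cycle genes fell in 25 of 52 and rose in 2 (adjusted p = 5.21e-05), and ribosome biogenesis genes fell in 21 of 38 and rose in 1 (1.95e-05). Genes of the p53 response fell in 12 of 27 with 0 higher (adjusted p = 0.000436) and histone genes rose in 9 of 21 with 0 lower (0.000256), but these lists had adjusted p-values of 0.0657 and 0.153 with an estimated correlation. The other 12 lists did not pass. Adjusted over the list alone, lower counts were 27 for cell cycle, 23 for ribosome biogenesis and 14 for p53 genes, with 1 p53 gene higher, and 18 cancer-testis genes were higher. Small differences in other lists are not printed here.

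In all, 3330 genes passed in limma, 1490 higher and 1840 lower, with 259 higher and 32 lower by 2-fold or more. Median scaling moved the median of all genes to −0.203 and the split to 708 higher and 2326 lower, and cyclic loess gave 1665 higher and 1297 lower. Chip 1 alone gave 792 genes and chip as a block 4062.

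**Figure D4:**
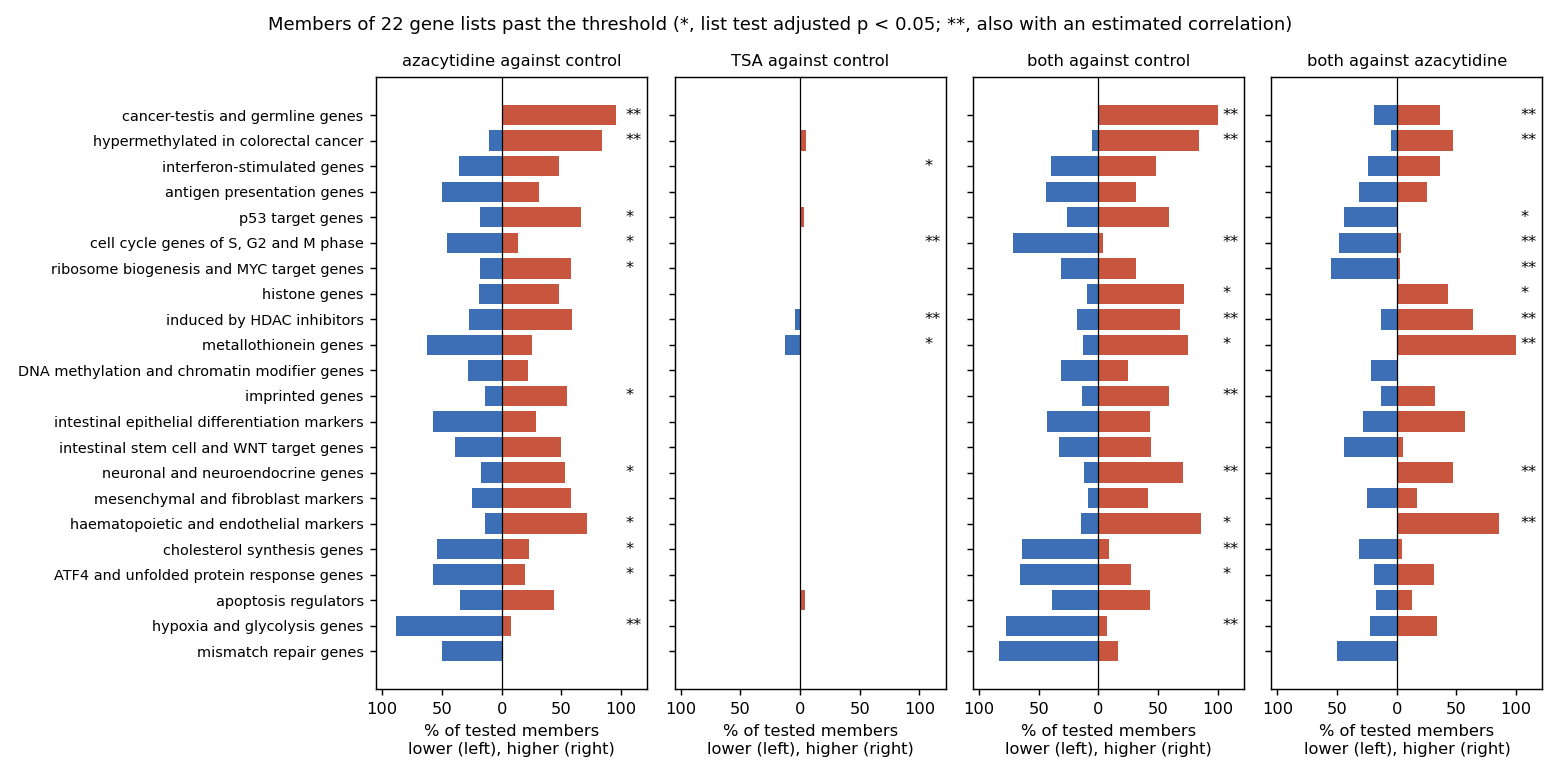
Percent of the tested members of each of 22 gene lists that passed the threshold in limma, higher to the right and lower to the left, for 4 comparisons. Asterisks mark lists that passed the list test, and double asterisks those that also passed with an estimated correlation. Cancer-testis genes rose in 45 of 47 after azacytidine and metallothionein genes in 8 of 8 between the combined treatment and azacytidine.

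The interaction asked whether the combined change differed from the sum of the single changes on the log2 scale, and 2150 genes passed in limma, 1097 higher and 1053 lower than that sum, with 349 by 2-fold or more. Of these 349 genes, 301 lay above the sum and 48 below it. PMEL lay above the sum by 4.02 ± 0.12 SE (adjusted p = 7.65e-10), LGALS1 by 3.56 ± 0.11 SE, VGF by 3.27 ± 0.11 SE, HBA2 by 3.22 ± 0.19 SE and SYT11 by 3.11 ± 0.20 SE. Below the sum lay SPATA18 (−1.72 ± 0.13 SE), TGFBI (−1.61 ± 0.14 SE), the prostaglandin receptor gene PTGER2 (−1.50 ± 0.16 SE), SLC39A1 (−1.50 ± 0.15 SE) and ACYP2 (−1.43 ± 0.17 SE). Of 22 lists, 9 passed, with metallothionein genes above the sum in 6 of 8 (adjusted p = 5.67e-07) and cell cycle genes below it in 24 of 52 and above it in 1 (2.46e-07). The histone list (adjusted p = 0.0149) had an adjusted p of 0.296 with an estimated correlation, and the other 8 also passed that way. The histone call was also lost without the filter on dim probes (0.179, mean shift 0.08 against 0.26), at a detection p of 0.05 (0.19) and without TSA replicate 3 (0.0579). Adjusted over the list alone, 7 metallothionein genes lay above and 32 cell cycle genes below. Median scaling gave 436 higher and 1152 lower, with the median of all genes at −0.251. Cyclic loess gave 1241 higher and 664 lower. Chip 1 alone gave 520 genes and chip 2 alone 558, with single arrays standing for some groups. PMEL, HBA2, SYT11, SPATA18 and TGFBI were detected on no control array, so the size of their interaction depends on the background correction. If the combined cells were also cultured longer, which the labels do not settle, the interaction holds that difference too.

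The TSA changes without and with azacytidine did not correlate across genes (r = −0.07, rho −0.08, no arrays shared). Changes after TSA alone had an SD of 0.148 log2 beside a median SE of 0.104, so noise weakens this correlation. It does not show whether the responses to TSA differ. Azacytidine and TSA against the same control arrays shared 9 genes called in the same direction, against 3.88 higher and 0.62 lower for independent lists, and 3 genes were called in opposite directions. The correlation of their changes was 0.09. Unchanged groups simulated against shared controls gave 0.50. That value cannot be set beside 0.09, since real azacytidine changes spread widely (SD 0.884 log2), which lowers a correlation. The covariance was 0.0122, against 0.00711 simulated. With 3 control arrays the controls could not be split, so part of any excess may come from the shared controls.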

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

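The tests of array noise, of the histone deacetylase inhibitor list, of hypoxia genes outside glycolysis and of single-copy germline genes were chosen after the results they bear on had been seen. The others were written down first.

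A difference between groups was found by the interaction test: 2150 genes changed differently after azacytidine with TSA than without. Of 100 regroupings of the 12 arrays, 2 gave as many genes, the real one included, and 1 other regrouping gave 2701. That regrouping put 3 arrays with azacytidine in the place of the combined group and 0 in that of the azacytidine group, so it measured the azacytidine difference itself. All 99 other regroupings mixed arrays with and without azacytidine within groups, which widens the spread and lowers the count, so they do not show whether chance can be excluded. The largest differences were PMEL at 4.02, LGALS1 at 3.56, VGF at 3.27, HBA2 at 3.22 and SYT11 at 3.11 above the sum, and SPATA18 at −1.72, TGFBI at −1.61, PTGER2 at −1.50, SLC39A1 at −1.50 and ACYP2 at −1.43 below it. Another 57 of 109 other named genes passed the interaction test, 31 higher and 26 lower, against 22.7% of all tested genes. The rule named genes mainly for their changes on these same arrays, so no excess over that share is read from this count.

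By list, the median interaction was 1.15 for metallothionein genes, 0.54 for genes induced by histone deacetylase inhibitors, 0.45 for neuronal genes, 0.42 for haematopoietic and endothelial markers, 0.23 for histone genes and 0.16 for cancer-testis genes. It was −0.34 for p53 target genes, −0.36 for cell cycle genes and −0.36 for ribosome biogenesis genes. The histone list did not pass with an estimated correlation (adjusted p = 0.296) or without the filter on dim probes (0.179).

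Few genes changed after TSA alone, and many more between the combined treatment and azacytidine (14 and 3330). Noisier arrays are argued against, since the median within-group SD of the TSA and control arrays was 1.12 times that of the other arrays. TSA that was not active in the cells behind the TSA arrays, or untreated RNA under that label, stays open: the list of genes induced by histone deacetylase inhibitors had a median change of −0.10 after TSA alone, on that reading's side of a bound set after the value had been seen, and 0.46 between the combined and azacytidine arrays. Whether the combined cells were cultured longer than the azacytidine cells is not given in the labels. If they were, longer culture cannot be told apart from TSA by this design, and of 291 genes changed by 2-fold or more between those groups 19.2% had not been changed by azacytidine alone, between the bounds set for either reading. A response to TSA that needs prior azacytidine is a biological hypothesis, and stays open with both.

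Hypoxia and glycolysis genes fell after azacytidine. Normalization pushing bright genes down is argued against, since none of 10000 random lists matched on control level had a median as low (percentile 0), and their 2.5th percentile was −0.23. Lower hypoxia-inducible transcription may account for the pattern and stays open: the 13 members that are not glycolytic enzymes had a median of −0.72 and 76.9% of them fell, short of the share set for that reading, while 14 of 14 glycolytic enzymes fell with a median of −0.86. Oxygen and medium use were not measured here, and a difference in time in culture between the groups is not settled.

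Cancer-testis and germline genes rose after azacytidine. Probes shared between near-identical family members are argued against as the whole cause, since among single-copy germline genes on no control array 11 of 25 (44.0%) were detected on all azacytidine arrays, 8.18 times the share of genes outside the list (two-sided Fisher's exact test, p = 2.67e-08). Silent genes of any kind switching on alike is argued against too. Among genes on no control array, 35 of 75 list members (46.7%) were detected on all azacytidine arrays. Of 9977 other genes 5.38% were, a ratio of 8.67 (two-sided Fisher's exact test, p = 3.41e-24). That p takes near-identical family members as independent, so it is too small, which the single-copy count avoids. A selective response of germline genes to azacytidine is a hypothesis found and tested on the same data.

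The splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05, and in each comparison 1 of them, the real one, gave as many genes as observed. The counts were 6023 for azacytidine, 14 for TSA, 6541 for the combined treatment against control, 6617 against TSA and 3330 against azacytidine, with 0 in the highest other split of each. Every other split mixed arrays of both groups, which widens the spread and lowers the count where the groups differ. The other splits therefore do not show whether chance can be excluded.

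A signal also appeared in probes without a gene name here. Of 21211 such probes, 179 were detected on all azacytidine and no control arrays, 11 on all TSA and no control arrays, and 223 on all combined and no control arrays. The lower detection on control arrays may favour such counts.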

How the results depend on the processing

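No named gene or list past its threshold changed direction past it under the 21 kinds of alternative, but the balance of higher and lower genes did turn. Median scaling gave mostly lower genes for azacytidine and the interaction (37.8% and 27.5% higher, against 50.9% and 51.0%), and cyclic loess mostly higher genes for the combined treatment against control, TSA and azacytidine (54.0%, 55.2% and 56.2%, against 47.5%, 47.9% and 44.7%), as did the 2-fold limit (57.0%, 58.0% and 89.0%) and, for the last, chip 1 alone (63.8%). The shares for azacytidine and the interaction lay near even and also turned under other settings. Without counting left-out arrays, values of named genes stayed the same in 3284 cases, lost their call in 47, gained it in 7 and moved in 18, and those of lists in 1842, 40, 40 and 36. A limit of 2-fold left 1289 genes for azacytidine, 3 for TSA, 1660 and 1661 for the combined treatment against control and against TSA, 291 against azacytidine and 349 for the interaction. An adjusted p of 0.01 left 0 for TSA, 2131 for the combined treatment against azacytidine, 1110 for the interaction and 0 genes shared by azacytidine and TSA. TSA gave 0 genes on chip 1 alone and 0 on chip 2 alone, as did the overlap, and 4 with only the 6 arrays compared. The combined treatment against azacytidine gave 792 on chip 1 alone, and the interaction 520 on chip 1 and 558 on chip 2, with fewer arrays in each fit and a lone array of a group taken to vary like the others. Leaving out each array gave 0 (without TSA replicate 2) to 24 (without control replicate 2) genes for TSA and 0 to 17 for the overlap. The correlation of azacytidine changes was 0.865 without the probe filter and 0.866 on chip 1 alone. Lists passing after azacytidine numbered 3 with an estimated correlation. After TSA they numbered 7 under median scaling, 7 under cyclic loess, 2 without the probe filter, 2 on chip 1, 1 on chip 2 and 2 with an estimated correlation. Apart from the thresholds, the smaller fits and the estimated correlation, the cause was not tested. With the replicate block the counts were 6313 for azacytidine, 12 for TSA, 6831, 6898 and 3752 for the combined treatment against control, TSA and azacytidine, and 2591 for the interaction. For the combined treatment against azacytidine, where same-numbered arrays also share a chip, 10 lists passed with that block. Over all comparisons the same-number deviation correlations lay between −0.292 and 0.428. Arrays on the same chip deviated together (median r 0.23) and those on different chips apart (−0.22), and with chip as a block 14 of 14 TSA genes, 3328 of 3330 and 2149 of 2150 genes of the last comparisons kept their direction and call. Probes near background limit the small changes of dim genes.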

Other observations

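Genes grouped by the start of their symbol were tested after the data had been seen, over 292 groups with at least 5 tested genes, and of those passing with the preset correlation none passed with an estimated correlation (adjusted p from 0.174 to 0.509). All 5 tested genes with BEX symbols were detected on all 3 azacytidine arrays and on no control array. They entered the test only through arrays with azacytidine, so their joint rise was favoured by the filter. Genes whose symbols begin with RPL, mostly ribosomal proteins of the large subunit but also pseudogenes and RPL7L1, fell in 32 of 50 and rose in 6 after azacytidine (median −0.43, adjusted p = 0.00212, and 0.174 with an estimated correlation). Their median was −0.43 without background correction, −0.69 under median scaling and −0.45 under cyclic loess.

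Between the combined treatment and azacytidine, genes whose symbols begin with LGALS, which are galectins and the galectin-binding protein gene LGALS3BP, rose in 4 of 6 (median 1.42, adjusted p = 0.0293, and 0.509 with an estimated correlation), and under median scaling 3 rose and 2 fell. Beta-tubulin genes rose in 5 of 6, with TUBB2B at 1.44, and in 3 of 6 under median scaling (median 0.27 against 0.47).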
